A study of Mus musculus with 2 samples.

How the data were processed

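Tumour-infiltrating Tregs of C57BL/6 mice 8 to 12 weeks old were profiled by droplet single-cell RNA sequencing of transcript 3' ends. Per the labels' protocols, tumours were digested, lymphocytes were enriched on a density gradient, Tregs were selected with magnetic beads and sorted by a fluorescent signal, and libraries followed a 10x Genomics 3' protocol. The labels do not give the tumour model, the number or sex of the animals, the driver of the deletion or the exons removed. Each of the 2 groups, WT and cKO, has 1 library, assigned from the genotype label.

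The deposited files hold raw UMI counts per gene and cell barcode, with gene identifiers, symbols and barcodes in companion files that carry no measurement. Per the file headers and the submitters' processing notes, the authors made the counts with Cell Ranger 5.0.1 on genome build mm10. The annotation release, the use of reads in introns, any filter before deposit and any doublet removal are not given in the sources used here. The matrices list 32285 gene identifiers, of which 32158 were matched to GENCODE mouse M21 on the same build; coordinates come from that annotation.

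Barcodes with at least 500 detected genes and under 10% mitochondrial UMIs were kept. Of 3905 WT barcodes 3842 passed, and of 4105 cKO barcodes 4026. Scrublet, run per library with an expected doublet rate of 5%, marked 1 of 7868 barcodes (0.0127%), so it gave no usable call here, and any doublets left in the deposited matrices remain. As a substitute chosen after seeing the data, results were recomputed without the highest 5% of Scrublet scores in each library. The analysis kept 3841 WT and 4026 cKO cells, with medians of 9085 and 6953 UMIs and of 2.31% and 2.30% mitochondrial UMIs.

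Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen after Jmjd1c, T cell receptor and immunoglobulin segments, ribosomal protein genes, mitochondrial genes, Xist and Y-linked genes had been left out. Tsix was not left out. Cells were joined through 30 principal components and 15 neighbours and clustered with the Leiden algorithm at resolution 0.6 (scanpy 1.11.5, python-igraph 0.11.9). No batch correction was applied, since the library is the group. Markers of 17 cell types were fixed before the data were examined; the scoring rule was set afterwards. A cluster took the type with the highest share of markers detected at 10 CPM and at 25% or more of the highest cluster. Markers shared between types were left out of the scoring, and genes of the Treg lists were not counted for other types. A cluster stayed unnamed with under 3 detected markers, or where its top 10 genes by fold against cells of other types held at least as many markers of another type as of its own, unless there were none of another type. It also stayed unnamed where its median UMI count was under 1/3 of that of its library and no marker of its type was among the top 10. Against all other cells in place of cells of other types, the top 10 genes of 4 Treg-like clusters held markers of other types (Calca; Trdc and Igkc; Gzmb and Ccr2; Il1rl1) and none of Tregs. Directions within each of the 8 Treg-like clusters are therefore given for the highest and lowest genes and for some others. They are signs of the log2 ratio without an interval, and a cluster can hold few cells of 1 library.

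Within a class, UMIs were summed per library and expressed as CPM with exact Poisson 95% intervals. Ratios have exact conditional binomial 95% intervals, without the pseudocount. Shares have exact Clopper-Pearson 95% intervals. All cover counting error only. Log2 ratios are log2((CPM cKO + 5)/(CPM WT + 5)), which understates differences of low genes. For shares of cells with a UMI, cells were thinned to 4100 UMIs, the 10th percentile of Treg-like cells rounded down, and shallower cells were left out. With 1 library per group no p-value, standard error or count of changed genes was made.

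The genes named were fixed by rule before the data were examined. They are the 15 highest and 15 lowest log2 ratios in Treg-like cells among genes with a mean of at least 20 CPM, up to 4 members with the largest absolute log2 ratio in each of 23 gene lists, and 24 further genes. T cell receptor and immunoglobulin segments, mitochondrial genes, unnamed gene models, Xist and Y-linked genes were outside the ranking. Not every gene under the rule is given in the text; 1 of the 15 highest and 1 of the 24 further genes were left out after their values were seen, for a reason unrelated to the values. Il7r, Ccr7, Ccr6, Pmaip1 and Bax are named in addition where a list's members went apart, after their values were seen, as are Lyz2 and the genes given for other cell classes. A list's median was taken over members with a mean of at least 5 CPM and placed among 10000 random lists of the same size drawn from 20 expression bins. A list was said to stand apart below the 2.5 or above the 97.5 percentile.

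The calculation was tested on simulated counts of 5174 genes with the means and depths of the Treg-like sums, 200 of them changed. For 1.5-fold and 2-fold changes, 96.5% and 97.5% of the intervals held the true ratio and 100% of the changed genes were given in the right direction. Of 200 unchanged lists 4.5% lay beyond the percentiles, over 8641 genes. The simulated counts were Poisson, the model the intervals assume, without spread between animals or libraries and without genes that vary together. They check the calculation and give no rate of false calls for the real lists.

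Alternatives were a looser filter of 200 genes, a stricter one of 1000, Scrublet-marked cells kept, Leiden resolutions 0.3 and 1.0, all kept cells, only cells with a Foxp3 UMI, no proliferation-led cluster, median-of-ratios scaling, TMM scaling (edgeR 4.0.16, R 4.3.3), a mean over cells scaled to equal totals, equal cluster composition, thinned cells, a pseudocount of 1 CPM and other minimum levels. Adding the globin-led cluster, and using only clusters with at least 100 cells in each library, were added after seeing the data. The latter pools the cells of 3 clusters, which the libraries fill unequally. Equal cluster composition weights the CPM of each Treg-like cluster by its share of the Treg-like cells of both libraries together. Some clusters are led by the genes compared and hold few cells of 1 library, which limits this setting. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.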

Results

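Single-cell transcriptomes were collected from regulatory T cells (Tregs, CD4 T cells that depend on the transcription factor Foxp3 and restrain immune responses) that had entered tumours of C57BL/6 mice 8 to 12 weeks old. One library came from wild-type animals (WT) and 1 from animals in which Jmjd1c had been deleted in Tregs (cKO). Jmjd1c encodes a protein with a JmjC domain, the catalytic domain of a family of histone lysine demethylases. The WT matrix held 3905 cell barcodes and 49063944 UMIs (unique molecular identifiers, 1 per captured transcript), with a median of 8946 UMIs and 2572 genes per barcode. The cKO matrix held 4105 barcodes and 37666195 UMIs, with a median of 6884 UMIs and 2201 genes. With 1 library per group no test across animals exists. Every interval below is a 95% interval that covers counting error only, exact Poisson for levels and exact binomial for shares, and a difference between the libraries has no replicate check.

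The targeted gene, Jmjd1c (ENSMUSG00000037876, chromosome 10, 67096125 to 67256326, plus strand, mm10), was read first. In Treg-like cells it stood at 93.8 CPM (UMI counts scaled to a common total; 90.5 to 97.1; 3139 UMIs) in WT and 76.3 CPM (72.8 to 79.9; 1790 UMIs) in cKO, so that the cKO level was 81.3% of WT (76.7 to 86.2). In monocyte or macrophage-like cells, where the deletion is not meant to act, cKO stood at 72.2% of WT (62.9 to 82.9), and in CD8 T-like cells at 105% (84.6 to 132). After thinning each cell to 4100 UMIs, 33.0% of 2964 WT and 27.5% of 2501 cKO Treg-like cells held a Jmjd1c UMI, against 32.2% and 18.6% of monocyte or macrophage-like cells. The labels do not give the deleted exons, and tags from the 3' end of the transcript can lie outside them, so these levels check neither the deletion nor the genotype labels. Pooled over the 3 clusters with at least 100 cells in each library, the log2 ratio was -0.05 in place of -0.28. This setting was chosen after seeing the data. The libraries fill these clusters in unequal numbers, and Jmjd1c was lower in cKO within each of them. The log2 ratios there were -0.15, -0.52 and -0.20, with intervals spanning 0 for the first and last. By sign, Jmjd1c was lower in 7 of the 8 Treg-like clusters.

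By their sex-linked transcripts, the libraries came from animals of different sex as well as different genotype. Xist, the RNA that coats the inactive X chromosome of female cells, had 42924 UMIs in kept WT cells (97.1% of cells) and 46 in kept cKO cells (0.273%). Y-linked transcripts (Ddx3y, Eif2s3y, Uty or Kdm5d) were found in 74.6% of 4026 cKO cells (73.2 to 75.9) and in 0 of 3841 WT cells (upper limit 0.096% for cells with a captured UMI). Sex and genotype cannot be separated in any comparison given here.

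Cells of both libraries were clustered together, which gave 16 clusters, and clusters were named from fixed markers. Treg-like cells made up 81.1% of kept WT cells (79.9 to 82.4; 3116 of 3841) and 73.3% of kept cKO cells (71.95 to 74.7; 2953 of 4026). Cells outside the intended sort were more frequent in cKO. CD8 T-like cells (cytotoxic T cells) made up 2.68% in WT (2.19 to 3.24) and 10.2% in cKO (9.29 to 11.2). Monocyte or macrophage-like cells made up 4.74% in WT (4.09 to 5.46) and 11.03% in cKO (10.1 to 12.0), but 2.45% and 7.68% at Leiden resolution 1.0 and 2.29% and 7.27% with a minimum of 1000 genes. NK-like cells numbered 5 in WT (0.130%) and 86 in cKO (2.14%), whereas dendritic-like cells made up 1.43% in WT and 0.472% in cKO. Fibroblast-like and neutrophil-like cells stayed below 0.3% in each library. Unnamed clusters held 9.40% of WT and 2.36% of cKO cells. Most of these were cells of 1 cluster with Treg markers led by globin genes, at 8.77% of WT and 2.06% of cKO cells, which a naming rule set after seeing the data kept out of the Treg-like class. All these shares follow a magnetic selection and a fluorescence sort and may be set by them.

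**Figure D1:**
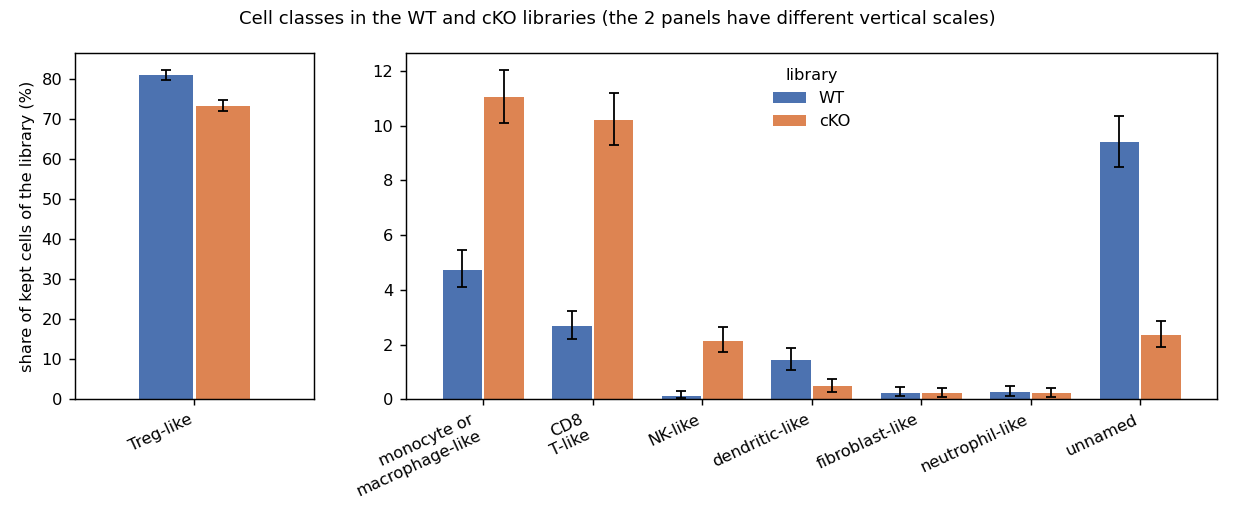
Share of kept cells (vertical axis, percent of the library) in each named class and in unnamed clusters, for the WT (blue) and cKO (orange) library. Bars are the share in 1 library and lines its exact binomial 95% interval, covering counting error only; Treg-like cells stand at 81.1% in WT and 73.3% in cKO, CD8 T-like cells at 2.68% and 10.2%.

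Treg-like cells fell into 8 clusters, and different clusters held most of them in each library. A cluster led by Xist, Cystm1, Rgs2 and Calca held 64.2% of WT Treg-like cells and 2.07% of those from cKO. A cluster led by Gzmb, Lag3, Il10 and Cd27 held 2.70% in WT and 38.7% in cKO. A cluster led by Gadd45g, Il1rl1, Batf and Ebi3 held 0.449% and 21.4%, and a cluster led by S1pr1, Klf2 and Socs3 held 6.10% and 21.7%. The leading genes of these clusters themselves differed between the libraries, so the clusters may be the library rather than cell states, and their sizes are given here to show what the Treg-like sums contain. Proliferation genes led a cluster with 10.1% of WT (9.10 to 11.3) and 8.20% of cKO Treg-like cells (7.23 to 9.24). Interferon-response genes such as Ifit3 led a cluster with 4.75% and 2.51%, and heat-shock genes led a cluster with 7.28% and 5.05%. A small cluster led by Igfbp7 and Tmem176a held 4.43% and 0.406%.

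The main comparison asked how the transcripts of tumour Tregs differed when Jmjd1c was deleted in them. UMIs were summed over Treg-like cells, 33468414 in WT and 23461924 in cKO, and compared as log2((CPM cKO + 5)/(CPM WT + 5)). Gzmb encodes the cytotoxic protease granzyme B (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260). It stood at 595 CPM (587 to 604) in WT and 4401 CPM (4374 to 4428) in cKO. Its log2 ratio of 2.88 was the highest among ranked genes with a mean of at least 20 CPM. Outside that ranking, which leaves out sex-linked transcripts, the Y-linked Ddx3y (4.19) and Eif2s3y (4.13) lay higher. Xist (-7.54) lay lower than any ranked gene. Il10, an anti-inflammatory cytokine of Tregs, stood at 25.3 CPM (23.7 to 27.1) in WT and 98.5 CPM (94.6 to 103) in cKO. Lag3, an inhibitory receptor that binds MHC class II, stood at 87.4 and 296 CPM, and Socs3, a feedback inhibitor of cytokine signalling, at 58.2 and 229 CPM. Gzmb, Socs3, Foxp1, Cd27, Igtp, Ms4a4b, Arl5c, Tesc and Mmp9 were higher in cKO within each of the 8 Treg-like clusters, Lag3 within 7 of 8, Ly6c2 within 6 of 8 and Il10 within 5 of 8. Such counts of clusters, here and below, use the sign alone, without an interval. Clusters held as few as 14 WT or 12 cKO cells, so a sign there can rest on few UMIs. Also among the 15 genes highest in cKO by the fixed rule were Gpr18 (1.83) and Igsf23 (1.73), each higher within 7 of 8 clusters. The log2 ratios of Ly6c2, Tesc, Foxp1, Mmp9, Ms4a4b, Arl5c, Igtp and Cd27 were 2.09, 1.96, 1.58, 1.58, 1.53, 1.51, 1.51 and 1.496. Ly6c2 stood at only 10.97 and 63.1 CPM in Treg-like cells, against 832 and 803 CPM in cKO CD8 T-like and monocyte or macrophage-like cells, which were more frequent in cKO.

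Among the 15 lowest genes in cKO were Itga4, which encodes the integrin alpha 4 chain used in tissue entry, at 196 CPM (191 to 200.3) in WT and 30.2 CPM (28.0 to 32.5) in cKO, and Rgs2, a regulator of G-protein signalling, at 674 CPM (665 to 682) and 176 CPM (171 to 182). Itga4, Rgs2, Cystm1, Ier5l, Oxct1, Hist1h4d, Tsix and the non-coding RNA gene AY036118 were lower in cKO within all 8 Treg-like clusters. Tff1 and Hist2h2ac were lower within 7 of 8, Ttn and Hist1h3c within 6, Hist1h1b and Hist1h2ab within 5 and Tnfsf8 within only 4, with the other 4 higher. AY036118 had the lowest log2 ratio among ranked genes, -3.62, from 388 to 27.1 CPM. The Xist antisense gene Tsix (-3.46) and the trefoil factor gene Tff1 (-2.96) followed. The other lowest genes were Cystm1 (-1.95), Ier5l (-1.86), the TNF family ligand gene Tnfsf8 (-1.74), Oxct1 (-1.67), Ttn (-1.63) and 5 histone genes, Hist1h3c (-2.01), Hist1h2ab (-1.98), Hist1h1b (-1.70), Hist2h2ac (-1.65) and Hist1h4d (-1.57). The 30 genes kept their direction in every alternative tried, but not their rank. Over all kept cells 2 of the 15 highest and 13 of the 15 lowest stayed in place, and at equal cluster composition 6 and 8. With cluster composition held equal between the libraries, 18 of the 30 still differed at least 2-fold, among them Rgs2 (-1.04). Gzmb (0.93), Lag3 (0.99), Socs3 (0.82), Il10 (0.22) and Tnfsf8 (-0.28) no longer did. Gzmb, Lag3 and Il10 led 1 of the clusters held equal, and Socs3 was among the leading genes of another. Part of their difference may therefore be taken out by the setting itself. Clusters with as few as 14 WT or 12 cKO cells also count in it. Without the proliferation-led cluster Hist1h2ab stood at -0.18 and Hist1h3c at -0.53, and Ly6c2 moved from 2.09 to 1.13.

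Many of these genes differed the same way in cells that were not Tregs. Beyond counting error, 14 of the 15 lowest genes were lower in cKO CD8 T-like cells and 14 in cKO monocyte or macrophage-like cells, 7 of the 15 at least 2-fold in both. The intervals of Hist1h3c in CD8 T-like cells (5 and 5 UMIs) and of Tnfsf8 in monocyte or macrophage-like cells spanned 0. AY036118 stood at 303 and 23.6 CPM in CD8 T-like cells of WT and cKO, and Rgs2 at 652 and 154 CPM. Beyond counting error, 12 of the 15 highest genes were higher in cKO CD8 T-like cells, all but Il10, Lag3 and Mmp9, and 13 in monocyte or macrophage-like cells, with Ly6c2 and Tesc at least 2-fold higher in both. Il10 stood at 19.6 and 19.2 CPM in monocyte or macrophage-like cells, and Mmp9 at 53.0 and 4.44 CPM. For Gzmb the log2 ratio was 0.78 in CD8 T-like cells (1559 and 2677 CPM) and 1.64 in monocyte or macrophage-like cells (282 and 886 CPM). Differences between classes have no replicate check. For genes higher in cKO, free RNA or doublets from Treg-like cells were not told apart from expression in these classes.

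**Figure D2:**
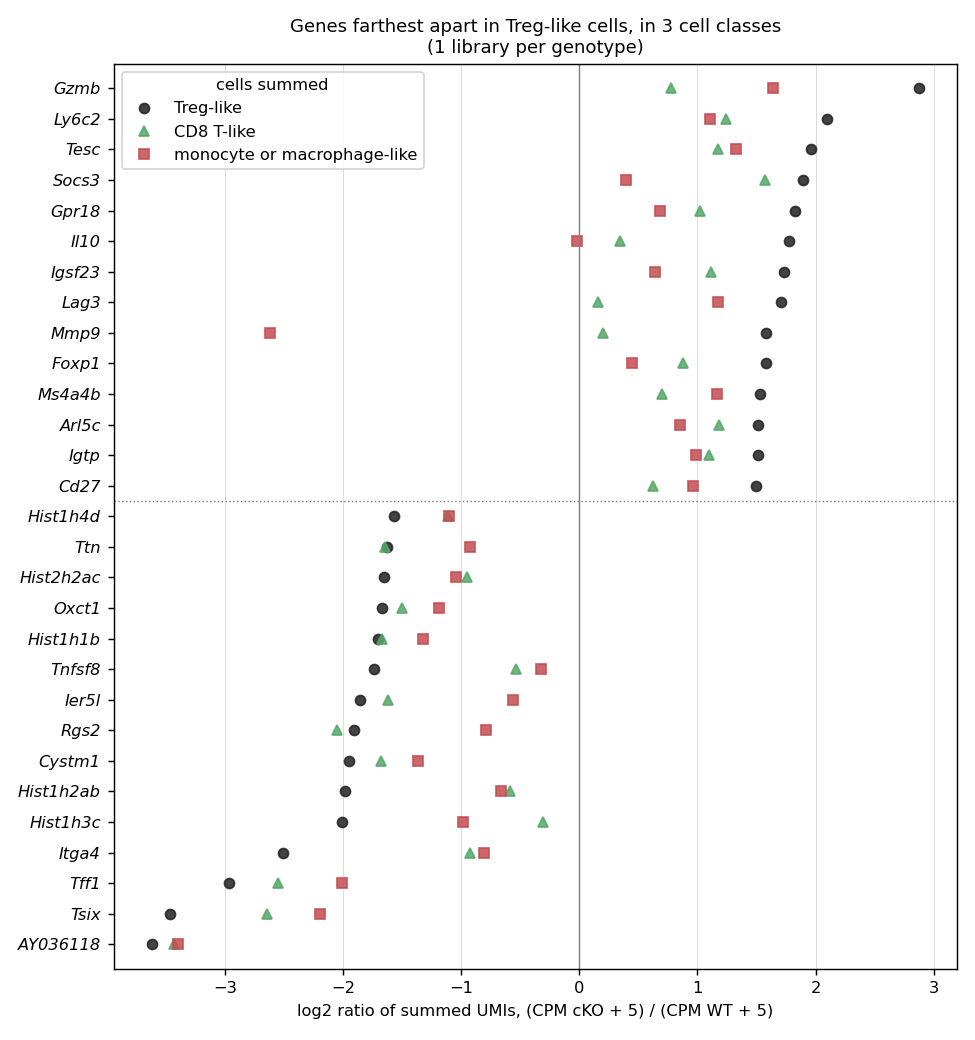
Log2 ratio of summed UMIs, cKO over WT with 5 CPM added to each (horizontal axis), for the 15 highest and 15 lowest ranked genes in Treg-like cells. Xist and Y-linked genes were not ranked, and 1 of the highest is left out of the plot. Circles are Treg-like, triangles CD8 T-like and squares monocyte or macrophage-like cells, 1 value per gene from 1 library per genotype; triangles lie on the same side of 0 as the circles for every gene shown, and squares for all but Il10 (-0.02) and Mmp9 (-2.62).

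Among genes fixed in advance, Pdcd1, which encodes the inhibitory receptor PD-1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), was lower in cKO, at 483 CPM (476 to 491) in WT and 207 CPM (201 to 213) in cKO. Its log2 ratio of -1.20 became -0.55 at equal cluster composition, and it was lower within 6 of 8 clusters. Foxp3 was higher in cKO, at 39.4 CPM (37.3 to 41.5) and 60.5 CPM (57.4 to 63.8), within 7 of 8 clusters. Ctla4, a receptor that removes costimulatory ligands, stood at 1288 and 2090 CPM, Icos, a costimulatory receptor, at 996 and 1826 CPM, and Tgfb1, a suppressive cytokine, at 371 and 535 CPM. Ifng, the cytokine of type 1 responses, stood at 21.6 CPM (20.1 to 23.2) in WT and 42.8 CPM (40.1 to 45.5) in cKO. Its log2 ratio of 0.84 became 0.19 over the 3 clusters with at least 100 cells in each library, pooled without balance between clusters. The interleukin-2 receptor chain gene Il2ra had a log2 ratio of 0.30, which turned to -0.27 at equal cluster composition, and was higher within 4 and lower within 4 of 8 clusters. Log2 ratios were 0.53 for Tnfrsf4, 0.35 for Tnfrsf9 and -0.31 for Stat3, and 0.71 for Tcf7 at levels of only 3.65 and 9.16 CPM. They were -0.15 for Ikzf2, -0.52 for Bcl2, -0.44 for Mki67 and -0.22 for Ccr8. Stat3 and Bcl2 were lower within only 4 of 8 clusters, Ikzf2 and Mki67 within 5 and Ccr8 within 3. Foxo1 (0.01) and the 2 relatives of Jmjd1c, Kdm3a (0.00) and Kdm3b (-0.14), had similar levels in both libraries.

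Shares of cells with a UMI were compared after thinning to 4100 UMIs, which left out 152 WT and 452 cKO Treg-like cells. The remaining Treg-like cells had medians of 8264 UMIs in WT and 6898 in cKO before thinning. Monocyte or macrophage-like cells thinned to the same depth served as a rough measure of free RNA. Their medians before thinning were higher, 22848 and 14565.5 UMIs, which dilutes free RNA and would make this background too low for Treg-like cells. Doublets, or expression by these cells themselves, would make it too high. In WT, Il2ra stood in them at 46.0% of its Treg-like level. None of these sources was measured, so the direction of the error is not known for each gene. Gzmb was detected in 35.9% of WT (34.2 to 37.7) and 86.4% of cKO Treg-like cells (84.96 to 87.7), and in 20.5% and 36.03% of monocyte or macrophage-like cells; unthinned, the Treg-like shares were 44.5% and 88.7%. Il10 was detected in 6.38% and 21.6% of Treg-like cells and in 5.26% and 4.17% of monocyte or macrophage-like cells. In CD8 T-like cells it was detected in 2.94% (3 of 102 cells) and 4.18%. The WT Treg-like share thus lay near that of monocyte or macrophage-like cells, whose own Il10 was not told apart from free RNA. Unthinned Il10 shares in Treg-like cells were 9.21% and 27.6%. Pdcd1 was detected in 71.6% and 36.4% of Treg-like cells (unthinned 82.6% and 44.9%), against 24.0% and 10.0% in monocyte or macrophage-like cells. Foxp3 was detected in 15.5% and 21.8% (unthinned 30.1% and 33.9%; background 3.51% and 2.94%), and Ifng in 6.28% and 9.24% (unthinned 10.4% and 13.0%; background 1.75% and 2.45%). For Mki67 the shares were 14.7% and 10.996% (unthinned 21.5% and 14.5%; background 4.09% and 4.17%), and for Ccr8 6.61% and 4.72% (unthinned 13.7% and 9.01%; background 0.58% and 0.49%). Ctla4 was detected in 91.5% and 93.1% (unthinned 95.6% and 95.3%; background 40.9% and 31.9%), and Tnfrsf9 in 96.9% and 96.4% (unthinned 98.9% and 96.9%; background 54.4% and 39.5%). Ccr7 was detected in 22.3% and 20.7% (unthinned 27.4% and 23.1%; background 15.8% and 12.3%). Lyz2, a macrophage gene, was detected in 1.55% of WT and 8.24% of cKO Treg-like cells, beside the higher share of monocyte or macrophage-like cells in cKO.

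Gene lists fixed in advance were described by the median log2 ratio of their measured members and its percentile among 10000 random lists matched on expression, as a description of these libraries. Some genes, such as Gzmb, Il10, Lag3, Ctla4 and Batf, are members of more than 1 list, so the lists are not independent. Counts of members higher or lower use the sign of the log2 ratio alone. The list of Treg core identity genes was higher in cKO, with a median of 0.30 (percentile 98.9) and 9 of 13 members higher, such as Entpd1 (0.58), the ectonucleotidase CD39, while Nrp1 (-1.16) and Nt5e (-0.75) were lower. At equal cluster composition its median was -0.11. Tumour effector Treg genes had a median of 0.46 (percentile 100) and 13 of 17 members higher, among them Il1rl1 (1.06), the interleukin-33 receptor, the transcription factor Batf (0.96) and the integrin gene Itgae (0.89). At equal cluster composition this list (0.061) and costimulatory receptors (0.14) no longer stood apart. Suppressive mediators had a median of 0.55 (percentile 100) with 9 of 12 members higher, Ebi3 (0.83), Lag3, Il10 and Gzmb among them. Costimulatory receptors had a median of 0.50 (percentile 99.95) with 10 of 11 members higher, Cd27 and Slamf6 (0.55) included, and Cd226 (-1.13) as the exception. In CD8 T-like cells the medians of these 4 lists were -0.20, 0.08, 0.00 and 0.05, and in monocyte or macrophage-like cells -0.17, -0.05, 0.32 and 0.12. Suppressive mediators thus stood apart in monocyte or macrophage-like cells too (percentile 99.62). Gzmb and Lag3 stood at 886 and 71.0 CPM in these cKO cells, against 4401 and 296 CPM in cKO Treg-like cells. Free RNA or doublets from Treg-like cells were therefore not told apart from expression there. Inhibitory receptors went the other way, with a median of -0.23 (percentile 0.77): 8 of 12 members were lower, led by Tox (-1.28), a transcription factor of chronically stimulated T cells, and Pdcd1, while Lag3 and Ctla4 were higher. Their medians were -0.20 in CD8 T-like and -0.32 (percentile 0.25) in monocyte or macrophage-like cells. Over the 3 clusters with at least 100 cells in each library, pooled without balance between clusters, the Treg-like median was 0.00.

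Lists tied to cytokine signals were read next. STAT3 target genes had a median of 0.56 (percentile 100) and 12 of 16 members higher, including Pim1 (1.37), Bcl3 (1.34) and Socs3. This list also stood apart in CD8 T-like (0.22, percentile 99.07) and monocyte or macrophage-like cells (0.26, percentile 99.18). STAT5 target genes had a median of 0.48 (percentile 100) with 8 of 10 members higher, among them Socs1 (0.93) and Cish (0.55), both feedback inhibitors, and medians of 0.23 (percentile 97.78) and -0.06 in the other classes. Cish, Pim1, Osm and Bcl6 are in both STAT lists. The interferon response list had a median of 0.43 (percentile 100), and 22 of its 26 members were higher, led by the GTPase genes Igtp (1.51), Gbp2 (1.21), Gbp4 (1.11) and Gbp3 (1.05). It was also higher in CD8 T-like (0.34) and monocyte or macrophage-like cells (0.52). Th1 and effector cytokine genes had a median of 0.43 (percentile 100) with 13 of 16 higher, including Il12rb2 (0.96), and medians of 0.59 and 0.58 in the other classes. Ccl4, a member of that list, had a log2 ratio of 1.31 that turned to -0.94 at equal cluster composition, and was higher within 4 and lower within 4 of 8 clusters. Only 3 of 11 Th2 and Th17 cytokine genes were measured (median 0.52, percentile 99.1), Il1rl1 and Gata3 (0.52) higher and Ccr6 lower. That list no longer stood apart over all kept cells (0.36), over cells with a Foxp3 UMI (0.033) or in thinned cells (0.40), and it stood apart in CD8 T-like (0.896) and monocyte or macrophage-like cells (1.04). AP-1 and NF-kB components had a median of 0.45 (percentile 99.99) with 11 of 15 higher, among them the inhibitor gene Nfkbia (0.85), and Rel (-0.85) lower. They stood apart in CD8 T-like (0.499, percentile 100) and monocyte or macrophage-like cells (0.22, percentile 97.77) as well. Apoptosis and survival genes, taken as 1 list, had a median of 0.33 (percentile 99.96) and 13 of 16 members higher, including the death receptor gene Fas (1.10), Bcl2l11 (0.52) and the survival genes Mcl1 (0.56) and Birc3 (0.59). The survival gene Bcl2 (-0.52) and the death genes Pmaip1 (-0.30) and Bax (-0.08) were lower. At equal cluster composition the list had a median of 0.13 and did not stand apart, whereas it did in CD8 T-like cells (0.21, percentile 98.54).

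Resting and FOXO1 target genes, which mark recirculating T cells, had the highest median, 0.84 (percentile 100), with 8 of 10 members higher by sign. Of these, 7 had a log2 ratio of at least 0.5, and Foxo1 (0.01) had similar levels in both libraries. Foxp1, Klf2 (1.33) and Satb1 (1.33) were among them, whereas the interleukin-7 receptor gene Il7r and the homing receptor gene Ccr7 were lower. CD8 T-like cells had a median of 0.88 for this list. Proliferation genes were lower, with a median of -0.30 (percentile 0.00) and 19 of 22 members lower, such as H2afz (-0.72), Top2a (-0.44) and Birc5 (-0.41), and a median of -0.47 in CD8 T-like cells. At equal cluster composition the median was 0.07. Fatty acid metabolism genes were lower, with a median of -0.25 (percentile 0.39) and 13 of 14 members, including Elovl6 (-0.35) and Hadha (-0.28). The list no longer stood apart in 5 of 19 alternatives, for example with members of at least 20 CPM (-0.12, percentile 10.81).

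The remaining lists did not stand apart from random lists. AKT and mTORC1 target genes had a median of 0.11 (percentile 84.99), with Sqstm1 (0.70) and Slc3a2 (0.43) higher and the transferrin receptor gene Tfrc (-0.70) lower. Early response genes of TCR signalling had a median of 0.11 (percentile 78.7), with Nfkbid (0.95) and Myc (0.79) higher and Nr4a2 (-1.03) lower, the last within only 4 of 8 clusters. Dissociation and stress genes had a median of 0.19 (percentile 94.7), and the heat-shock genes Hspa8 (1.14), Hspa1a (1.08), Hspa1b (0.87) and Dnajb1 (0.75) were higher. This list did stand apart, as higher, in 7 of 19 alternatives, for example over all kept cells (0.40, percentile 100). Hspa8 was higher by about as much in CD8 T-like (0.998) and monocyte or macrophage-like cells (1.03). Oxidative phosphorylation genes had a median of -0.06 (percentile 8.45) and cholesterol biosynthesis genes -0.13 (percentile 9.02), with Cyp51 at -0.70. Chemokine receptors and homing genes had a median of 0.01 (percentile 45.9) with members far apart, from Ccr2 (1.43) to Cx3cr1 (-1.19) and Itga4 (-2.51). Hypoxia genes had a median of -0.15 (percentile 4.60), with Ero1l at -0.56 and Egln3 at 0.60. Lysine demethylases, the family of Jmjd1c, had a median of -0.05 (percentile 33.2), with Kdm6b at 0.69 and the X-linked Kdm6a at -0.76.

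**Figure D3:**
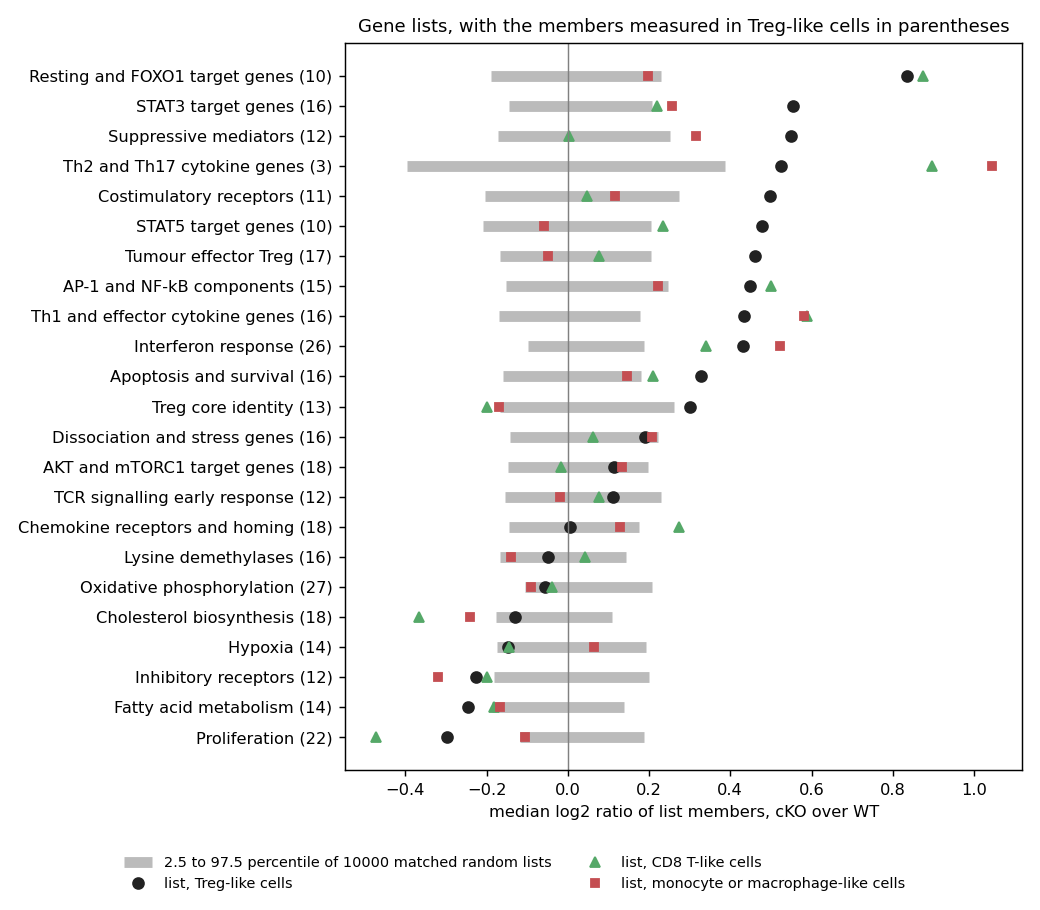
Median log2 ratio, cKO over WT (horizontal axis), of 23 gene lists in Treg-like (circles), CD8 T-like (triangles) and monocyte or macrophage-like cells (squares); grey bars span the central 95% of 10000 random lists matched on expression in Treg-like cells. Resting and FOXO1 target genes lie highest in Treg-like cells (0.84) and proliferation genes lowest (-0.30).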

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

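The tests on neighbouring cells were written before their results were seen; the tests on Gzmb, on free RNA from Treg-like cells and on chromosomes were chosen after the result was seen. Xist, outside the ranked genes, stood at 877 CPM over all kept WT cells and 1.23 CPM over kept cKO cells, and 74.6% of kept cKO cells held a Y-linked UMI against none of 3841 WT cells. A UMI of both kinds was found in 9 cKO cells and in no WT cell. The direction of Mmp9 differed between cell classes, with a log2 ratio of 1.58 in Treg-like cells and -2.62 in monocyte or macrophage-like cells (222 and 30 UMIs); the difference was not tested.

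One pattern was that Treg-like cells of the libraries lay in different clusters. Among equal numbers of Treg-like cells from each library, 86.5% of the 15 nearest neighbours came from the same library, where full mixing gives 50%. After thinning to equal depth the share was 87.2%, which argues against the difference in UMIs per cell. The share was also high where Jmjd1c is not meant to be deleted, 79.8% in CD8 T-like and 64.6% in monocyte or macrophage-like cells. A difference that every cell type shares would give this. So could free RNA or doublets from Treg-like cells. In WT, Treg markers stood in these classes at up to 52.2% and 46.0% of their Treg-like level. The shares therefore cannot show a difference in the other cells themselves. The separation may come in part from the animals, their sex or the library. An effect of Jmjd1c loss in Tregs on the other cells of the tumour stays open as well.

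Another pattern was the higher level of Gzmb in cKO Treg-like cells. Free RNA from CD8 T-like or NK-like cells is argued against, since Gzmb was 4.96 times higher in cKO Treg-like than in cKO monocyte or macrophage-like cells, more than their depths (medians of 6210 and 13873.5 UMIs) would dilute it; Gzma, at 8100 CPM in cKO NK-like cells beside 4363 CPM of Gzmb, stood at only 21.9 CPM in cKO Treg-like cells. A single factor for this transcript in the whole library stays open: the log2 ratio in CD8 T-like cells (0.78) was lower by 2.10 than in Treg-like cells, but Gzmb in Treg-like cells stood at 0.93 with equal cluster composition. Sex and genotype cannot be told apart, since cKO Treg-like cells had 0.298 CPM of Xist and no library of the other sex exists within a genotype. Loss of Jmjd1c thus remains one of several open explanations.

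A further pattern was that most of the 15 genes lowest in cKO Treg-like cells, 14 in each class beyond counting error, were lower in the other classes. Free RNA from Treg-like cells can carry their transcripts into other droplets, and no single ratio was seen. Treg markers stood in WT CD8 T-like cells at 24.0% (Izumo1r) to 52.2% (Ikzf2) of their level in Treg-like cells. For 3 of the 15 genes, AY036118, Rgs2 and Ier5l, the drop in CPM in CD8 T-like cells was larger, beyond counting error, than free RNA at the highest marker share could bring. In monocyte or macrophage-like cells this holds for AY036118 alone. The share at which these genes are carried over was not measured, so the test cannot exclude free RNA there. For the other 12 free RNA and a difference in the cells themselves cannot be told apart. AY036118 had log2 ratios of -3.43 in CD8 T-like and -3.40 in monocyte or macrophage-like cells, close to -3.62 in Treg-like cells. The cause was not tested. Doublets could not be called, so they were not told apart from free RNA. Sex stays open too: 1 of the 15 genes, Tsix, lies on the X chromosome, and autosomal genes can also differ by sex.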

How the results depend on the processing

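The limits come from the design: 1 library per group, sex that moves with genotype, libraries of unequal depth, doublets that could not be called, and a naming rule set after seeing the data, whereas markers, gene lists and the rule for naming genes were set before the data were examined. No paired analysis was possible because each group has 1 library. The settings without the highest 5% of Scrublet scores, with the globin-led cluster, and over clusters with at least 100 cells in each library were chosen after seeing the data; the other settings were set before. No setting shifted the median log2 ratio of all genes by more than 0.1, the largest shift being 0.057 with median-of-ratios scaling. The lists of resting and FOXO1 target genes (medians 0.37 to 1.11 over the alternatives), suppressive mediators (0.23 to 0.62), STAT3 (0.18 to 0.63) and STAT5 target genes (0.24 to 0.67), interferon response (0.37 to 0.62), Th1 and effector cytokine genes (0.19 to 0.54) and AP-1 and NF-kB components (0.37 to 0.60) stood apart in the same direction in all 19 alternatives. For every result below that was not kept, the cause was not tested.

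With equal cluster composition the median of Treg core identity was -0.11, of chemokine receptors and homing -0.14 and of proliferation 0.072, each of opposite sign to the result given. This setting conditions on clusters whose leading genes include list members, and some of these clusters hold few cells of 1 library. In the same setting tumour effector Treg genes had a median of 0.061, costimulatory receptors 0.14, apoptosis and survival 0.13, fatty acid metabolism -0.16 and lysine demethylases -0.17. Over all kept cells Treg core identity had a median of 0.088, inhibitory receptors -0.18, Th2 and Th17 cytokine genes 0.36, dissociation and stress genes 0.40 and hypoxia -0.17. Over only cells with a Foxp3 UMI, Th2 and Th17 cytokine genes had 0.033, TCR signalling early response 0.35 and dissociation and stress genes 0.39. Without the proliferation-led cluster, Treg core identity had 0.24, proliferation -0.14 and fatty acid metabolism -0.18. In cells thinned to equal UMIs, Treg core identity had 0.26, Th2 and Th17 cytokine genes 0.40 and proliferation -0.14.

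As a mean over cells scaled to equal totals, Treg core identity had a median of 0.22, fatty acid metabolism -0.15 and hypoxia -0.18. With list members of at least 20 CPM, inhibitory receptors had -0.14, fatty acid metabolism -0.12 and chemokine receptors and homing 0.28, and with no minimum CPM hypoxia had -0.18. Over clusters with at least 100 cells in each library, inhibitory receptors had 0.0027, of opposite sign to the result given, dissociation and stress genes 0.26, oxidative phosphorylation -0.13, cholesterol biosynthesis -0.30, hypoxia -0.19 and the Jmjd1c log2 ratio was -0.0510. Within each of these clusters Jmjd1c was lower in cKO, and the pooled cells were not balanced between clusters. Dissociation and stress genes had 0.27 with the looser filter of 200 genes, 0.24 without the highest 5% of Scrublet scores, 0.26 at Leiden resolution 0.3 and 0.27 with the globin-led cluster. With a minimum of 1000 genes fatty acid metabolism had -0.18. Of the 15 lowest genes 8 were kept at a mean of at least 50 CPM, and of the 15 highest 10. Over all kept cells 13 of the lowest and 2 of the highest were kept, and with equal cluster composition 8 and 6.

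The Treg-like share of kept WT cells was 89.7% at Leiden resolution 0.3, 88.6% with the filter of 200 genes, 78.4% with 1000 genes, 82.6% with Scrublet-marked cells kept and 85.6% without the highest 5% of Scrublet scores. The share of kept cKO cells was 75.5% at Leiden resolution 0.3, 70.6% at resolution 1.0 and 68.0% with 1000 genes.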

Other observations

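Monocyte or macrophage-like cells differed between the libraries as well. Genes here were picked from those farthest apart after their values were seen, and not strictly by size. Among genes with a mean of at least 100 CPM, the interferon-induced chemokine gene Cxcl9 stood at 364 CPM in WT and 1063 CPM in cKO, and Il1rn, which encodes the interleukin-1 receptor antagonist, at 190 and 649 CPM. The interferon-response genes Gbp2 (173 and 516 CPM) and Irf1 (80.9 and 220 CPM), the Fc receptor gene Fcgr4 (89.1 and 242 CPM) and the activin gene Inhba (54.9 and 162 CPM) were higher in cKO. So were the heat-shock gene Hspa1b (54.0 and 191 CPM), Upp1 (47.3 and 167 CPM) and Gzmb (282 and 886 CPM). Gzmb stood at 595 and 4401 CPM in Treg-like cells, so free RNA or doublets were not told apart from expression here. Mgl2 (201 and 53.0 CPM) and Chil3 (214 and 77.6 CPM) were lower, as were Penk (160.5 and 49.9 CPM) and Ctla2a (299 and 102 CPM), which are abundant in Treg-like cells. The counts rest on 182 WT and 444 cKO cells.

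CD8 T-like cells of cKO held more Gzmk (40.6 and 184 CPM), Gzma (117 and 501 CPM) and Ccl5 (1721 and 6076 CPM) than those of WT, and less of the granzyme genes Gzmf (806 and 76.2 CPM), Gzme (189 and 30.9 CPM) and Gzmc (401 and 132 CPM). The chemokine gene Xcl1 stood at 545 and 163 CPM, and Fcer1g, a signalling chain of NK and myeloid cells, at 182 and 20.2 CPM. The NK marker Klre1 was lower with them (195 and 77.6 CPM), and Gzmf and Gzmc stood at 5470 and 8505 CPM in cKO NK-like cells, so the composition of the class was not separated from a difference within CD8 T cells. These values rest on 103 WT and 411 cKO cells, with medians of 16980 and 8597 UMIs. Doublets among them could not be called.

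X-linked genes with a Y-linked partner or known escape from X inactivation were lower in cKO Treg-like cells: Kdm6a stood at 48.6 and 26.6 CPM, Eif2s3x at 50.02 and 26.7 CPM, Ddx3x at 114 and 79.7 CPM and Kdm5c at 33.4 and 24.5 CPM. Eif2s3x was lower in CD8 T-like (57.9 and 35.1 CPM) and monocyte or macrophage-like cells (51.6 and 33.2 CPM) as well. In monocyte or macrophage-like cells Kdm5c was not lower (32.7 and 34.04 CPM), and Ddx3x had a log2 ratio of -0.11 whose interval spanned 0. The 85 ribosomal protein genes had a median log2 ratio of -0.31 in Treg-like, -0.08 in CD8 T-like and -0.37 in monocyte or macrophage-like cells.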
